A study of Mus musculus with 24 samples.

How the data were processed

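RNA was sequenced from the renal cortex of 24 C57BL/6 mice in 4 groups of 6, per the labels: non-diabetic and diabetic mice, each given plain drinking water (called vehicle here) or the C5aR1 inhibitor PMX-53. The labels' protocols state that 200 ng of total RNA was depleted of ribosomal RNA and made into libraries with a directional kit. Reads were converted with bcl2fastq 2.20.0.422 and processed with STAR on the GRCm38 build, per the submitters' processing notes. The STAR version, the gene annotation, the counting tool and its strand setting are not given in the sources used here. Because the strand setting is not given, reads from a gene and an overlapping or antisense partner may not be separable, and members of families with near-identical copies or shared exons (Ugt1a, Cyp4a, C4a and C4b, the alpha-globin genes) are uncertain.

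The deposited table gives whole-number read counts per gene for the 24 libraries, not normalized, per the file headers and values. It holds 48526 genes, and 0 entries that name no gene. Each library held 10964992 to 22000895 counts, so low genes carry large counting error. Levels are given in CPM, the usual scaling of a count by library size, and 1 CPM rests on about 11 to 22 counts per library. Within groups, the 60 pairs of libraries differed beyond counting noise, with a chi-square of at least 5.65 per degree of freedom, and 0 pairs were identical.

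Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Genes were kept with edgeR's default expression filter over the 4 groups, which left 15808. Libraries were scaled by the trimmed mean of M-values (TMM). All 24 libraries entered 1 model with a coefficient per group and no covariates, fitted with edgeR's robust quasi-likelihood method. The quasi-likelihood F test gave p-values, which were adjusted by Benjamini-Hochberg over the 15808 genes, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Levels are normalized CPM, as mean ± SD over the 6 libraries of a group.

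There were 5 comparisons: diabetic against non-diabetic mice on vehicle, PMX-53 against vehicle in diabetic mice, PMX-53 against vehicle in non-diabetic mice, diabetic against non-diabetic mice on PMX-53, and the interaction. The interaction is the effect of PMX-53 in diabetic mice minus its effect in non-diabetic mice. The design, the alternatives and 56 gene lists (31 pathways, 21 sets of cell type markers and 4 sets for RNA quality) were fixed before the data were examined, except where stated. In each comparison 52 lists with at least 3 tested members were tested with limma's camera on voom values, with a preset correlation between genes of 0.01 and adjustment over the lists. Each list was tested again with the correlation estimated from the data, under which 0 lists passed in any comparison, and with fry, which asks whether a list's genes move 1 way on balance. Named genes follow a rule. It takes up to 8 rising and 8 falling genes with the largest log2 fold change among those past the threshold, with an average log2 CPM of at least 1 and a name that is not a gene model, small RNA or receptor segment. It adds up to 4 members with the smallest p of each list described, and C5ar1, C5ar2, Hc and C3. The genes Nnt, Ide, Wdfy1, Kap, Mdm2, Ccng1, Phlda3 and Igkv6-13 fall outside the rule and were chosen after their values were seen. Some genes that the rule takes are not reported here.

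Library properties were compared by exact two-sided permutation tests over 20 tests, adjusted by Benjamini-Hochberg. Both comparisons that use the diabetic vehicle libraries share them, so the share of genes with opposite signs was set against 20 simulated data sets without an inhibitor effect and recomputed over 20 divisions of these libraries into sets of 3. The alternatives were another scaling, no scaling, other filters, DESeq2, limma voom with sample quality weights, a replicate block, removal of mitochondrially encoded and ribosomal RNA genes, a 2-fold threshold, fits on only the groups compared, libraries thinned to the smallest total and libraries left out. The models were tested on simulated counts in which 200 of 15808 genes differed. For PMX-53 in non-diabetic mice the recovery was 72.9% of genes changed 1.5-fold and 91.8% of those changed 2-fold. For the interaction it was 46.9% and 83.7%. Gene positions come from the GRCm38 annotation (GENCODE M21) used here.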

Results

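The libraries profile RNA from the renal cortex of 24 mice that crossed streptozotocin diabetes with PMX-53 in 4 groups of 6. Streptozotocin is toxic to the insulin-producing beta cells, and PMX-53 is a peptide inhibitor of C5aR1, a receptor of the complement fragment C5a. The diabetic mice were injected with 55 mg/kg streptozotocin on 5 days from 6 weeks of age, whereas the non-diabetic mice received citrate. Animals of each kind were assigned at random to 2 mg/kg PMX-53 in the water or to water alone, and were followed for 24 weeks. The libraries held 10964992 to 22000895 counts. The labels name 24 separate samples, and p-values measure only the spread between these, part of which may be technical.

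RNA composition differed with diabetes on vehicle. Mitochondrially encoded genes took 29.5% ± 2.14 of the counts in the diabetic vehicle libraries and 22.6% ± 1.65 in the non-diabetic vehicle libraries (SD, n = 6 each, exact permutation p = 0.00216, the smallest possible, adjusted p = 0.0144). Ribosomal RNA took 28.1% ± 1.89 and 22.2% ± 1.81, and 22491 ± 449 and 21553 ± 228 genes were detected, with the same exact p and adjusted p. Both shares count the mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2, so they are not separate measures. With ribosomal RNA left out, mitochondrially encoded genes took 6.53% ± 0.450 and 4.86% ± 0.633 (exact p = 0.00216, not adjusted). The difference was then 1.66 percentage points, against 6.89 with ribosomal RNA. The shares of both groups were smaller as well, so the drop does not measure how much of the difference was ribosomal RNA. In 6 of 6 diabetic vehicle libraries the share of mitochondrially encoded genes, that of ribosomal RNA and the number of genes detected lay above the non-diabetic vehicle mean. Total counts were 18719832 and 14886578 on average (exact p = 0.0303, adjusted p = 0.0649). With PMX-53 in diabetic mice, 21856 ± 276 genes were detected, below the diabetic vehicle mean in 6 of 6 libraries (exact p = 0.00866, adjusted p = 0.0433). Total counts averaged 14885538 there, against 18719832 on vehicle (exact p = 0.0303, adjusted p = 0.0649). The number of genes detected depends on depth and was not compared at equal depth. It thus cannot show a change in composition here or between the vehicle groups. In diabetic PMX-53 libraries the mitochondrially encoded share was 25.8% ± 2.56 (exact p = 0.0260, adjusted p = 0.0649), and 5.48% ± 0.872 with ribosomal RNA left out (exact p = 0.0281, not adjusted).

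The lists of RNA quality gave further values. Small cytoplasmic and nuclear RNAs had a median log2 fold change of 0.53 with diabetes on vehicle, where 2 of 7 rose (2 adjusted over the list alone, camera adjusted p = 0.0548). With PMX-53 in diabetic mice the median was -0.46, and 4 of 7 fell (5 adjusted over the list alone, camera adjusted p = 0.0322, adjusted p = 0.415 with an estimated correlation). In the interaction it was -0.61, with 2 of 7 negative (3 adjusted over the list alone, camera adjusted p = 0.00634, adjusted p = 0.410 with an estimated correlation). Of nuclear long noncoding RNAs 1 of 5 rose and 2 fell with diabetes on vehicle (1 and 2 adjusted over the list alone, camera adjusted p = 0.448).

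The gene of the inhibitor's target, C5ar1 (ENSMUSG00000049130, chromosome 7, 16246743 to 16259540 on GRCm38), was scarce in the cortex, with 5 to 38 counts per library. Its log2 fold change was -0.34 ± 0.33 with diabetes on vehicle (edgeR adjusted p = 0.42) and 0.08 ± 0.34 with PMX-53 in diabetic mice (adjusted p = 0.892), and no comparison passed the threshold. C5ar2, the second receptor of C5a, had 139 counts over all libraries and was not tested. Hc, the gene of complement C5, had 26 counts and was not tested.

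Among vehicle mice, the cell cycle inhibitor gene Cdkn1a, the complement gene C3 and 3 genes of the Ugt1a cluster were higher with diabetes. The cluster encodes enzymes that conjugate glucuronic acid. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) went from 3.26 ± 1.19 to 39.2 ± 8.19 CPM, 11.9-fold higher (log2 fold change 3.57 ± 0.23, edgeR adjusted p = 3.47e-10). C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136), the central complement component, went from 17.2 ± 6.31 to 284 ± 182 CPM (log2 fold change 4.04 ± 0.54, adjusted p = 5.75e-06). In diabetic vehicle replicate 4, C3 lay at 29.5 CPM, against 164 to 537 in the 5 others. The collagen genes Col19a1 and Col6a6, the transporter gene Slco1a1 and Car3, a carbonic anhydrase, were lower with diabetes. Every named gene that passed in a pairwise comparison lay on its side of the reference group's mean in 6 of 6 libraries, except Havcr1 here and Cyp4a12a, Jchain and Cd8a with PMX-53 in diabetes, with 5 of 6.

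Of the largest rises, Ugt1a2 (ENSMUSG00000090171, chromosome 1, 88200601 to 88218997) had a log2 fold change of 6.48 ± 0.60, Ugt1a10 5.30 ± 0.58 and Ugt1a1 3.30 ± 0.34. These genes share exons, but the separate values are uncertain. Gc, which encodes the vitamin D binding protein, rose by 3.20 ± 0.39, Grem1, an antagonist of bone morphogenetic proteins, by 3.15 ± 0.44, and Eda2r, a receptor of the tumour necrosis factor family, by 3.14 ± 0.12 (log2, adjusted p = 1.99e-06, 5.97e-06 and 3.68e-17). Of the largest falls, Col19a1 fell by 4.29, Tmprss9 by 4.07, Cntnap5a by 3.91, Col6a6 by 3.72 and Pzp by 3.56 on the log2 scale. Slco1a1 fell by 3.48, Car3 by 3.16 and Anxa13 by 3.04 (adjusted p from 7.85e-09 to 8.35e-04 over these 8). Without diabetic vehicle replicate 4, whose levels of these genes lay nearest to those of non-diabetic mice, Col19a1 was at -5.25, Cntnap5a at -4.61, Pzp at -5.39 and Slco1a1 at -5.50. In diabetic vehicle libraries Col19a1 averaged 0.295 CPM, Tmprss9 0.311, Col6a6 0.350 and Cntnap5a 0.601. These levels rest on few counts, so the sizes of those falls are uncertain.

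Most tested nuclear genes of each respiratory chain list rose. In complex I, 27 of 36 genes rose and 0 fell (28 and 0 adjusted over the list alone, camera adjusted p = 2.08e-10, adjusted p = 0.277 with an estimated correlation), with Ndufa7 at 0.50 ± 0.06 and Ndufb8 at 0.49 ± 0.06. In complexes II and III, 9 of 14 rose (10 adjusted over the list alone, camera adjusted p = 1.21e-04, adjusted p = 0.368 with an estimated correlation), Uqcrq by 0.54 ± 0.07 and Uqcrb by 0.39 ± 0.05. In complex IV, 10 of 11 rose (10 adjusted over the list alone, camera adjusted p = 1.22e-06, adjusted p = 0.167 with an estimated correlation), with Cox7a2 at 0.47 ± 0.05 and Cox5b at 0.62 ± 0.08. In ATP synthase, 12 of 16 rose (13 adjusted over the list alone, camera adjusted p = 1.22e-06, adjusted p = 0.167 with an estimated correlation), with Atp5o at 0.58 ± 0.07. Cytosolic ribosomal protein genes rose in 39 of 42 cases (41 adjusted over the list alone, camera adjusted p = 2.55e-16, adjusted p = 0.277 with an estimated correlation), Rplp1 by 0.62 ± 0.07 and Rps16 by 0.54 ± 0.06. The same libraries had the higher mitochondrially encoded and ribosomal RNA shares given above, which overlap, and the median of small cytoplasmic and nuclear RNAs of 0.53.

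More genes of glycolysis and of tubular injury rose than fell. Of glycolysis genes 13 of 17 rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 1.62e-06, adjusted p = 0.136 with an estimated correlation), among them the pyruvate kinase gene Pkm at 1.08 ± 0.09 and the enolase gene Eno1 at 0.82 ± 0.08. Of gluconeogenesis and fructose genes 8 of 16 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0309, adjusted p = 0.417 with an estimated correlation), with Fbp2, a fructose bisphosphatase, at 1.29 ± 0.15. Of injury genes 14 of 24 rose and 3 fell (15 and 4 adjusted over the list alone, camera adjusted p = 0.00151, adjusted p = 0.417 with an estimated correlation). Spp1, the osteopontin gene, rose by 2.36 ± 0.27 and Havcr1, which encodes the injury marker KIM-1, by 1.34 ± 0.43, whereas the cytokine gene Il34 fell by 1.91 (log2).

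Most tested male-biased kidney genes and markers of the S3 segment of the proximal tubule fell. Of the androgen-responsive and male-biased genes, 11 of 12 fell (12 adjusted over the list alone, median log2 fold change -2.18, camera adjusted p = 4.57e-11, adjusted p = 0.167 with an estimated correlation), among them the cytochrome P450 genes Cyp4b1 at -2.20 ± 0.25 and Cyp4a12a at -2.64 ± 0.33, and Timd2 at -1.07 ± 0.10. Kap, the kidney androgen-regulated protein gene and chosen after its values were seen, went from 9811 ± 847 to 1323 ± 2093 CPM (log2 fold change -2.89 ± 0.61, adjusted p = 7.45e-04). Its level was 5556 CPM in diabetic vehicle replicate 4 and 145 to 1007 in the 5 others (-4.36 without that library). The fixed list of female-biased kidney genes moved the other way, with a median log2 fold change of 2.00. Of the S3 markers 5 of 7 fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.00360, adjusted p = 0.368 with an estimated correlation), with Slc22a7, an organic anion transporter gene, at -2.83 ± 0.42 (-3.72 without replicate 4) and Acy3 at -1.87 ± 0.26. B and plasma cell markers fell in 4 of 8 cases (4 adjusted over the list alone, camera adjusted p = 0.0330, adjusted p = 0.417 with an estimated correlation), with the immunoglobulin genes Jchain at -2.07 ± 0.31 and Igha at -2.19 ± 0.34. Red blood cell markers fell in 6 of 7 cases and rose in 1 (6 and 1 adjusted over the list alone, median -0.98, camera adjusted p = 0.0330, adjusted p = 0.521 with an estimated correlation).

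Most tested markers of the collecting duct and of the distal convoluted and connecting tubule rose, whereas those of the thick ascending limb moved both ways. Principal cell markers of the collecting duct rose in 7 of 8 cases (7 adjusted over the list alone, camera adjusted p = 0.00149, adjusted p = 0.368 with an estimated correlation), with the water channel gene Aqp2 at 1.72 ± 0.29 and the sodium channel gene Scnn1b at 0.61 ± 0.10. Distal convoluted and connecting tubule markers rose in 4 of 7 cases (4 adjusted over the list alone, camera adjusted p = 0.0330, adjusted p = 0.417 with an estimated correlation), with the calcium handling genes Calb1 at 1.04 ± 0.19 and Trpv5 at 0.78 ± 0.14. Intercalated cell markers rose in 6 of 9 cases (7 adjusted over the list alone, camera adjusted p = 0.00545, adjusted p = 0.368 with an estimated correlation), with Atp6v0d2 at 0.73 ± 0.09. Of the thick ascending limb markers 3 of 7 rose and 2 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.880), with a median of -0.17 and a mean of 0.04. The prostaglandin receptor gene Ptger3 was at 0.89 ± 0.14 and the claudin gene Cldn10 at -0.56 ± 0.07. Markers of the medulla and papilla, which the cortex samples could hold, rose in 5 of 8 cases (5 adjusted over the list alone, camera adjusted p = 0.00704, adjusted p = 0.417 with an estimated correlation). The urothelium list had 1 tested member, the uroplakin gene Upk1a, which rose by 1.39 ± 0.32 (log2). Liver markers rose in 2 of 5 cases (2 adjusted over the list alone, camera adjusted p = 0.132), with the transferrin gene Trf at 1.29 ± 0.20. Complement and matrix genes moved both ways. They comprised 5 of 28 complement genes up and 9 down (5 and 10 adjusted over the list alone), and 4 of 42 matrix genes up and 15 down (6 and 15 adjusted over the list alone). The lectin pathway protease genes Masp1 and Masp2 were at 2.58 ± 0.24 and -2.83 ± 0.42, Cfb at -1.0 ± 0.14, Timp3 at -1.21 ± 0.14 and Col6a3 at -0.87 ± 0.10. Masp2 averaged only 0.152 CPM in diabetic vehicle libraries. Of the renin-angiotensin genes, Agt, which encodes angiotensinogen, rose by 1.46 ± 0.16 and Ace fell by 1.60 (log2).

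By edgeR's quasi-likelihood test 6363 of 15808 genes differed between the vehicle groups, 3223 higher and 3140 lower, and 934 by at least 2-fold. Without scaling beyond library totals 31.2% of called genes were higher, against 50.7% with TMM. The diabetic vehicle libraries also stood apart from the 18 other libraries at single genes. Nnt, a transhydrogenase gene of the inner mitochondrial membrane (ENSMUSG00000025453, chromosome 13, 119335448 to 119408997), lay at 242 to 272 CPM there and at 101 to 121 CPM elsewhere. Ide, the insulin-degrading enzyme gene (ENSMUSG00000056999, chromosome 19, 37268743 to 37337852), lay at 62.2 to 76.5 against 111 to 169 CPM. Wdfy1 lay at 66.6 to 79.6 against 26.1 to 33.2 CPM. Another trait of this group cannot be told apart from diabetes in the comparison of the vehicle groups.

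**Figure D1:**
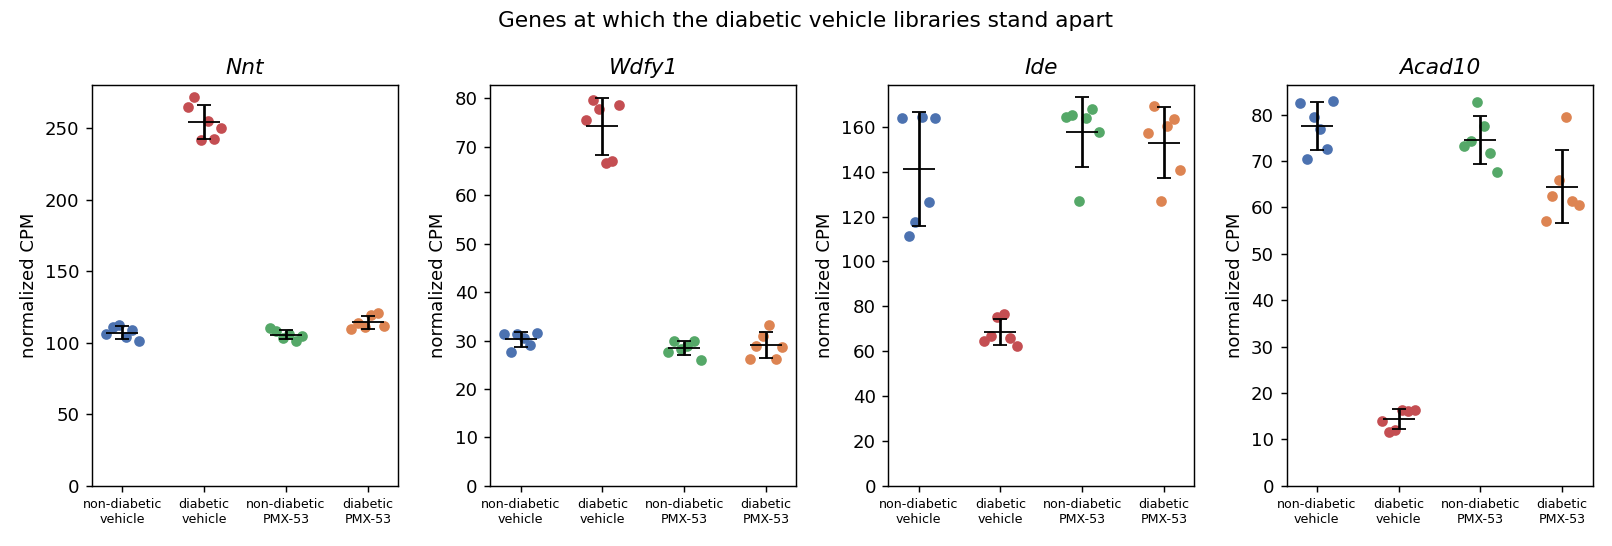
Normalized read counts in CPM of Nnt, Wdfy1, Ide and Acad10 in each of the 24 libraries, by group, with points for libraries and mean ± SD of 6. The 6 diabetic vehicle libraries hold 242 to 272 CPM of Nnt and the 18 others 101 to 121 CPM.

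**Figure D2:**
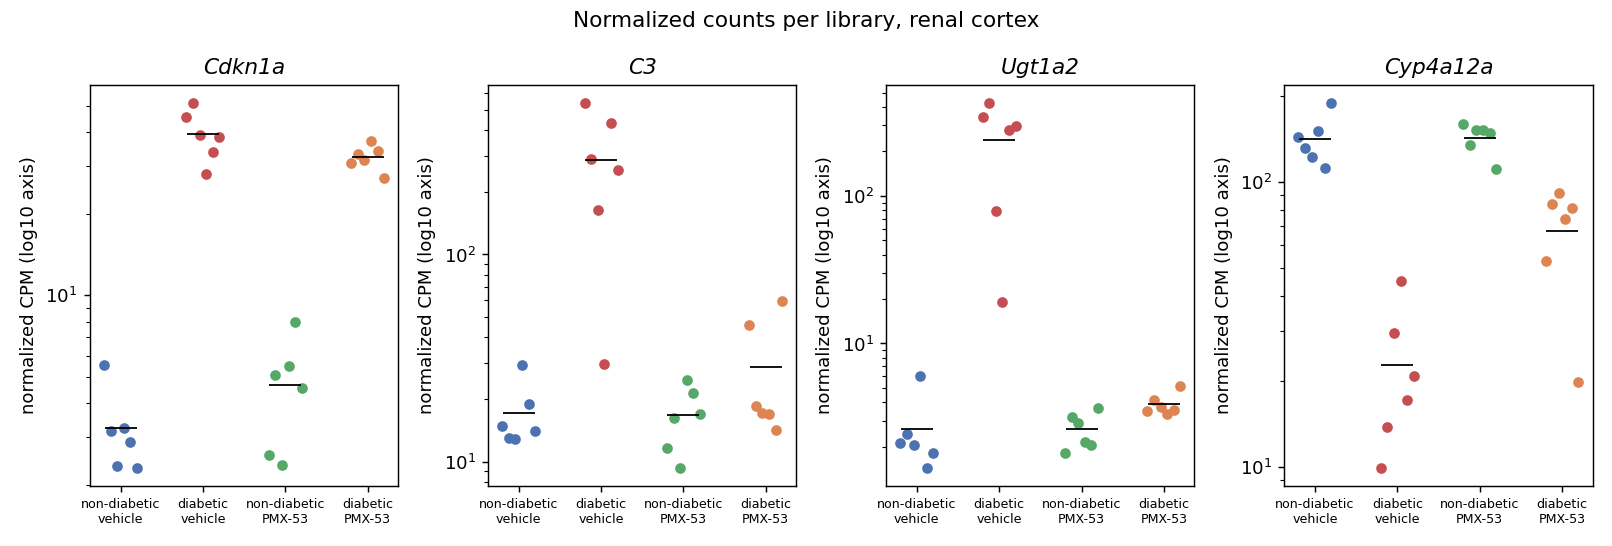
Normalized read counts in CPM (log10 axis) of Cdkn1a, C3, Ugt1a2 and Cyp4a12a in each of the 24 libraries, by group. Points are libraries and bars are means of 6, and Cdkn1a averaged 3.26 ± 1.19 CPM (mean ± SD) in non-diabetic vehicle and 39.2 ± 8.19 CPM in diabetic vehicle libraries.

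In diabetic mice on PMX-53, C3, Ugt1a1, Ugt1a2 and most tested nuclear respiratory chain and ribosomal protein genes were lower than on vehicle. In the same mice 11 of 12 male-biased kidney genes, 11 of 13 podocyte markers and 18 of 42 matrix genes were higher. The diabetic vehicle libraries, the reference here, stood apart from all others at single genes. A trait of that group, such as a substrain or exchanged labels, cannot be told apart from an effect of PMX-53 in this comparison. C3 went from 284 ± 182 to 28.7 ± 19.1 CPM (log2 fold change -3.32 ± 0.51, edgeR adjusted p = 8.89e-05) and Ugt1a2 from 239 ± 157 to 3.89 ± 0.656 CPM (log2 fold change -5.96 ± 0.57, adjusted p = 5.36e-07). In diabetic vehicle replicate 4, C3 lay at 29.5 CPM (164 to 537 in the 5 others), within the 14.2 to 59.7 of diabetic PMX-53 libraries. Ugt1a2 lay at 19.1 CPM in that library (79.3 to 424 in the 5 others). Havcr1 was 5.92-fold lower with PMX-53 (log2 fold change -2.57 ± 0.49, adjusted p = 5.39e-04). For Cdkn1a the log2 fold change was -0.28 ± 0.18 (adjusted p = 0.276) and did not pass.

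Other large falls were in Ndnf at -3.73 ± 0.62, Cyp4a14 at -3.28 ± 0.59, Slc7a12 at -3.21 ± 0.50, Nccrp1 at -2.93 ± 0.35, Ugt1a1 at -2.93 ± 0.33 and Gc at -2.80 ± 0.38 (log2). The largest rises were in the protease gene Tmprss9 at 3.61 ± 0.37 and in Col6a6 at 3.46 ± 0.63, Col19a1 at 2.5 ± 0.56, Slco1a1 at 2.29 ± 0.71, Ces2h at 2.29 ± 0.31, Acad10 at 2.16 ± 0.09, Pzp at 2.16 ± 0.59 and Cpxm1 at 2.12 ± 0.26. Without diabetic vehicle replicate 4, Col19a1 was at 3.45, Slco1a1 at 4.31 and Pzp at 3.98. The sizes of the rises in Tmprss9, Col6a6 and Col19a1 are uncertain, because diabetic vehicle libraries held few counts of these genes. Acad10 is 1 of the genes at which the diabetic vehicle libraries stood apart, at 11.6 to 16.4 CPM against 57.1 to 82.9 CPM in the 18 others.

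Respiratory complex I genes fell in 27 of 36 cases (29 adjusted over the list alone, camera adjusted p = 1.44e-14, adjusted p = 0.127 with an estimated correlation), Ndufa7 at -0.48 ± 0.06. Complexes II and III fell in 10 of 14 (11 adjusted over the list alone, camera adjusted p = 7.46e-07, adjusted p = 0.151 with an estimated correlation), Uqcrb at -0.48 ± 0.05. Complex IV genes fell in 10 of 11 (11 adjusted over the list alone, camera adjusted p = 5.46e-09, adjusted p = 0.0896 with an estimated correlation), Cox7a2 at -0.44 ± 0.05. Ribosomal protein genes fell in 37 of 42 cases (40 adjusted over the list alone, camera adjusted p = 3.41e-20, adjusted p = 0.134 with an estimated correlation), Rpl23 at -0.39 ± 0.06. Fatty acid oxidation genes fell in 15 of 31 cases and rose in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 4.27e-05, adjusted p = 0.408 with an estimated correlation), Eci1 at -0.76 ± 0.09. PPAR-alpha targets fell in 11 of 20 and rose in 3 (13 and 4 adjusted over the list alone, camera adjusted p = 0.00416, adjusted p = 0.395 with an estimated correlation), the thioesterase gene Acot3 at -1.82 ± 0.24. Injury genes fell in 9 of 24 and rose in 1 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00108, adjusted p = 0.268 with an estimated correlation), among them Cp, the ceruloplasmin gene, at -1.29 ± 0.19 and Spp1 at -1.42 ± 0.26.

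Podocyte markers rose in 11 of 13 cases (12 adjusted over the list alone, camera adjusted p = 2.92e-06, adjusted p = 0.127 with an estimated correlation), Podxl, the podocalyxin gene, by 0.44 ± 0.08. Matrix and fibrosis genes rose in 18 of 42 cases (19 adjusted over the list alone, camera adjusted p = 1.34e-05, adjusted p = 0.268 with an estimated correlation), with Col1a1 at 1.11 ± 0.20, Col6a3 at 0.71 ± 0.10 and Timp3, an inhibitor of metalloproteinases, at 0.78 ± 0.14. Endothelial markers rose in 5 of 13 (5 adjusted over the list alone, camera adjusted p = 0.00339, adjusted p = 0.268 with an estimated correlation), Kdr, the main VEGF receptor gene, by 0.58 ± 0.08. Male-biased kidney genes rose in 11 of 12 cases (11 adjusted over the list alone, camera adjusted p = 5.67e-09, adjusted p = 0.151 with an estimated correlation), Timd2 by 0.95 ± 0.10 and Cyp4a12a by 1.57 ± 0.32. Female-biased kidney genes had a median log2 fold change of -1.54. Red blood cell markers rose in 5 of 7 (6 adjusted over the list alone, camera adjusted p = 7.74e-04, adjusted p = 0.268 with an estimated correlation). Medulla markers fell in 5 of 8 (5 adjusted over the list alone, camera adjusted p = 0.00164, adjusted p = 0.256 with an estimated correlation). Liver markers fell in 4 of 5 (4 adjusted over the list alone, camera adjusted p = 0.00141, adjusted p = 0.0896 with an estimated correlation), with Trf at -1.17 ± 0.20. Markers of mesangial, smooth muscle and fibroblast cells rose in 6 of 12 (7 adjusted over the list alone, camera adjusted p = 9.27e-04, adjusted p = 0.236 with an estimated correlation), with Pdgfrb at 0.71 ± 0.15. B and plasma cell markers rose in 5 of 8 (5 adjusted over the list alone, camera adjusted p = 0.0591), with Igha at 1.36 ± 0.34. T and NK cell markers rose in 2 of 4 (3 adjusted over the list alone, camera adjusted p = 0.0699), with Cd8a at 1.22 ± 0.36 from low levels of 0.382 to 0.949 CPM. Upk1a was at -0.64 ± 0.29 and did not pass. All of these marker values come from the same libraries as the gene groups above, as does the median of -0.46 for small cytoplasmic and nuclear RNAs.

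In total 4317 of 15808 genes differed by edgeR, 2190 higher and 2127 lower, and 517 by at least 2-fold. Without scaling beyond library totals 79.5% of called genes were higher, against 50.7% with TMM, and the median log2 fold change of all genes was then 0.12.

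The diabetic vehicle libraries enter both comparisons with opposite signs. Of the 6363 genes called with diabetes on vehicle, 5826 (91.6%) had the opposite sign with PMX-53 in diabetic mice. Simulated data without an inhibitor effect gave 58.5% (56.9 to 59.7% over 20 data sets). With separate sets of 3 diabetic vehicle libraries for each comparison the median was 88.0% (79.5 to 92.1% over 20 divisions). The divisions remove only the noise of shared libraries. A trait common to all diabetic vehicle libraries would enter both comparisons with opposite signs, and the simulated data hold none. These shares and the counts below thus cannot tell such a trait from an effect of PMX-53. Genes up with diabetes and down with PMX-53 numbered 1559 where independent lists give 434, and those down and then up numbered 1562 where independent lists give 435. Independent lists leave out the shared libraries. The simulated data without an inhibitor effect, which leave out that effect, gave 0 genes in either direction in each of the 20 data sets. With separate sets of 3 diabetic vehicle libraries the medians were 924 (726 to 1050) where independent lists give 228, and 850 (577 to 1057) where they give 214. Across genes, which are not independent replicates, the log2 fold changes correlated at r = -0.79 (-0.48 simulated without any effect, -0.66 over the divisions). The covariance was -0.183, against -0.0146 simulated.

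PMX-53 in non-diabetic mice moved 0 of 15808 genes past the threshold by edgeR, with 0 by DESeq2 and 0 by limma voom with quality weights, and 1142 genes had an unadjusted p under 0.05. Without any effect a share of 0.05 of the 15808 genes would be expected there, so many of the 1142 can be due to chance. The smallest adjusted p was 0.327. C3 had a log2 fold change of -0.04 ± 0.53 and Cdkn1a of 0.50 ± 0.27 (adjusted p = 0.999 and 0.75). With no expression filter 1 gene passed, the immunoglobulin segment Igkv6-13, chosen after its value was seen (log2 fold change -3.83, adjusted p = 0.0389), with 47 counts in vehicle and 3 in PMX-53 libraries.

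With the preset correlation 11 lists passed in this comparison, and 0 passed by fry. Fatty acid oxidation genes had a median log2 fold change of -0.13 (0 of 31 rose and 0 fell over all genes tested, and 3 fell adjusted over the list alone, camera adjusted p = 8.94e-10, adjusted p = 0.436 with an estimated correlation), with Acadl, a mitochondrial acyl-CoA dehydrogenase gene, at -0.25 ± 0.07. Podocyte markers had a median of 0.23 (0 of 13 rose, 3 adjusted over the list alone, camera adjusted p = 1.33e-06, adjusted p = 0.164 with an estimated correlation), with Wt1, a podocyte transcription factor gene, at 0.50 ± 0.15. Distal tubule markers had a median of 0.29 (0 of 7 rose, 3 adjusted over the list alone, camera adjusted p = 2.06e-05, adjusted p = 0.164 with an estimated correlation), with Slc12a3, the thiazide-sensitive cotransporter gene, at 0.27 ± 0.09. No member of these lists passed over all genes. In simulated data of this comparison 91.8% of genes changed 2-fold and 72.9% of those changed 1.5-fold were recovered.

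Among mice on PMX-53, Cdkn1a and Eda2r and the distal nephron genes Trpv5 and Calb1 were higher with diabetes. Ly6e and the male-biased genes Odc1 and Cyp4b1 were lower. All diabetic mice had received streptozotocin, which cannot be told apart from diabetes here. Cdkn1a went from 4.69 ± 2.08 to 32.3 ± 3.31 CPM (log2 fold change 2.79 ± 0.22, edgeR adjusted p = 2.76e-08), and Eda2r from 1.03 ± 0.144 to 5.95 ± 0.374 CPM (log2 fold change 2.52 ± 0.12, adjusted p = 3.70e-14). Gdf15, a stress-induced secreted factor gene, rose by 1.09 ± 0.18 (log2, adjusted p = 3.25e-04). Ly6e went from 293 ± 21.2 to 106 ± 24.7 CPM (log2 fold change -1.47 ± 0.13, adjusted p = 1.71e-07). C3 was at 0.77 ± 0.52 (adjusted p = 0.388) and did not pass.

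Further rises were in Ugt1a10 at 3.15 ± 0.66, Dscaml1 at 2.93 ± 0.34, Fam212b at 2.2 ± 0.22, Pigz at 1.79 ± 0.25, Grem1 at 1.78 ± 0.44, the kynureninase gene Kynu at 1.81 ± 0.21 and Bhmt, which encodes the betaine methyltransferase of homocysteine, at 1.61 ± 0.18 (log2). Further falls were in Cntnap5a at -2.10 ± 0.32, Col19a1 at -1.66 ± 0.36, Apoh at -1.59 ± 0.44, Anxa13 at -1.56 ± 0.26, Angptl7 at -1.53 ± 0.41, Car3 at -1.40 ± 0.44 and Fcamr at -1.38 ± 0.31.

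Distal convoluted and connecting tubule markers rose in 4 of 7 cases (4 adjusted over the list alone, camera adjusted p = 0.00163, adjusted p = 0.40 with an estimated correlation), Trpv5 by 0.70 ± 0.14 and Calb1 by 0.82 ± 0.18. Intercalated cell markers rose in 2 of 9 (3 adjusted over the list alone, camera adjusted p = 0.00145, adjusted p = 0.40 with an estimated correlation), the proton pump gene Atp6v0d2 by 0.55 ± 0.09. Glycolysis genes rose in 3 of 17 (5 adjusted over the list alone, camera adjusted p = 0.00231, adjusted p = 0.40 with an estimated correlation), Pkm by 0.41 ± 0.09. Podocyte markers rose in 4 of 13 (5 adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.763 with an estimated correlation). Male-biased genes fell in 3 of 12 (7 adjusted over the list alone, camera adjusted p = 2.24e-05, adjusted p = 0.543 with an estimated correlation), with Odc1 at -0.91 ± 0.19. S3 markers fell in 2 of 7 (4 adjusted over the list alone, camera adjusted p = 0.00758, adjusted p = 0.535 with an estimated correlation), with Acy3 at -0.92 ± 0.25. Respiratory complex I genes had a median of -0.03, with 1 of 36 up and 0 down (0 and 0 adjusted over the list alone).

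By edgeR 1587 genes differed, 872 higher and 715 lower, and 150 by at least 2-fold. The count was 871 without scaling beyond library totals, where 65.7% were higher against 54.9%, and 2560 by limma voom with sample quality weights. The diabetes effects with and without PMX-53 share no library. They correlated at r = 0.592 across genes, and of the 6363 genes called on vehicle 5225 (82.1%) had the same sign on PMX-53. Over these genes the effect on PMX-53 had a slope of 0.337 on the effect on vehicle, in a fit through the origin. The genes were chosen by their call on vehicle, and selection and noise lower such a slope without any inhibitor effect. A trait of the diabetic vehicle libraries could lower it too, so the slope does not measure how far PMX-53 reduced the changes. Both comparisons called 1210 genes, 1190 of them in the same direction. Of these, 655 were up where independent lists give 178, and 535 were down where independent lists give 142.

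**Figure D3:**
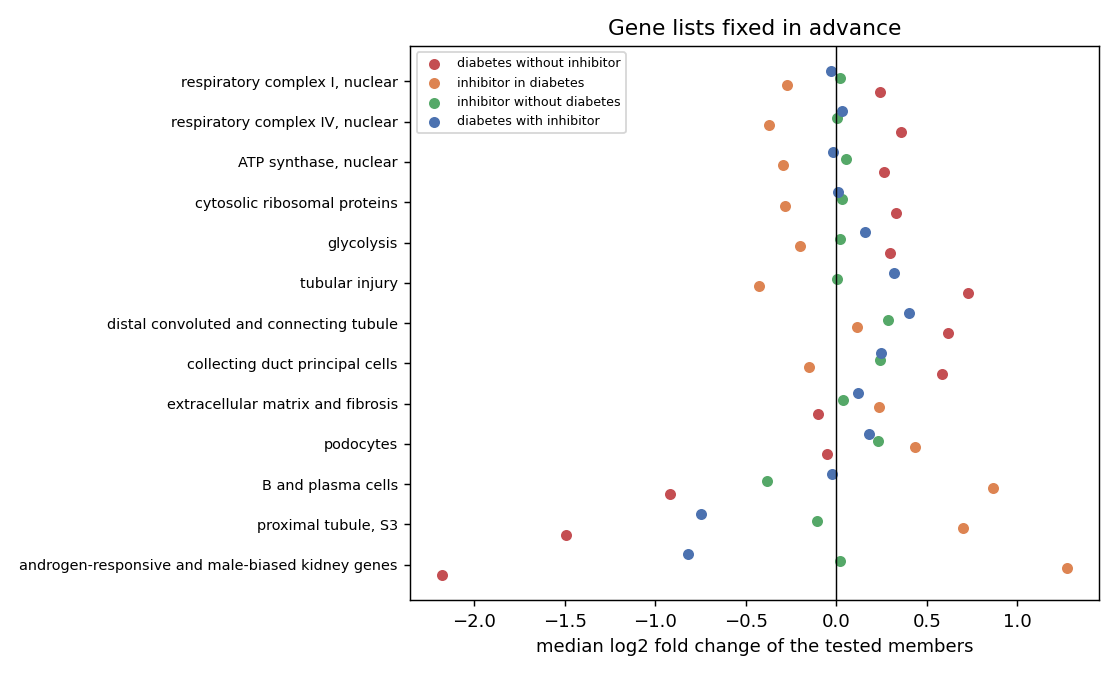
Median log2 fold change of the tested members of 13 gene lists (vertical axis) in the 4 pairwise comparisons (colours). For cytosolic ribosomal proteins the median was 0.33 with diabetes on vehicle, -0.28 with PMX-53 in diabetes and 0.03 with PMX-53 in non-diabetic mice.

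The interaction tests whether the effect of PMX-53 differed between diabetic and non-diabetic mice. A trait of the diabetic vehicle libraries would enter it as well and cannot be told apart from an effect of PMX-53. The difference between PMX-53 and vehicle was more negative in diabetic mice for C3, Ugt1a1, Ugt1a2, Cebpd and Ddit4. It was more positive for Tmprss9, Col6a6 and Acad10. C3 had an interaction log2 fold change of -3.28 ± 0.73 (edgeR adjusted p = 0.00779), Ugt1a2 of -5.93 ± 0.99 and Cebpd, a transcription factor gene of the C/EBP family, of -3.09 ± 0.57 (adjusted p = 0.00103 and 0.00196). Ddit4, which encodes an inhibitor of mTORC1 signalling, was at -2.78 ± 0.56. Wnt7b was at -3.05 ± 0.77, although 1 non-diabetic PMX-53 library held 7.42 CPM of Wnt7b against 0.614 to 1.21 in the others. Ugt1a1 was at -3.21 ± 0.53, Cyp4a14 at -2.71 ± 0.78 and Slc7a12 at -2.70 ± 0.73. Tmprss9 was at 3.50 ± 0.46, Col6a6 at 3.33 ± 0.78, Col19a1 at 2.64 ± 0.64, Ces2h at 2.54 ± 0.39, Acad10 at 2.22 ± 0.12, Cpxm1 at 2.05 ± 0.34, C4a, which shares sequence with C4b, at 1.94 ± 0.60 and Slc22a7 at 1.93 ± 0.56. Without diabetic vehicle replicate 4, Col19a1 was at 3.59 and Slc22a7 at 2.82, and Pzp, Slco1a1 and Kap passed as well, at 4.07, 4.24 and 3.51. The values of Tmprss9, Col6a6 and Col19a1 rest on few counts in the diabetic vehicle libraries.

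Respiratory complex I genes had a negative interaction in 20 of 36 cases (27 adjusted over the list alone, camera adjusted p = 3.60e-17, adjusted p = 0.107 with an estimated correlation), Ndufb8 at -0.48 ± 0.09. The interaction was negative for ribosomal protein genes in 27 of 42 (34 adjusted over the list alone, camera adjusted p = 1.90e-24, adjusted p = 0.110 with an estimated correlation), Rplp1 at -0.52 ± 0.09. Male-biased kidney genes had a positive interaction in 6 of 12 cases (10 adjusted over the list alone, camera adjusted p = 4.62e-10, adjusted p = 0.127 with an estimated correlation), Timd2 at 0.92 ± 0.14. It was positive for matrix genes in 9 of 42 (10 adjusted over the list alone, camera adjusted p = 0.00123, adjusted p = 0.473 with an estimated correlation), Col1a1 at 1.15 ± 0.28. Female-biased kidney genes had a median interaction log2 fold change of -1.57.

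At most 3 members of any cell type list passed for the interaction in the same libraries. Markers of mesangial, smooth muscle and fibroblast cells were positive in 3 of 12 (5 adjusted over the list alone, camera adjusted p = 0.00658), podocyte markers in 2 of 13 (2 adjusted over the list alone, camera adjusted p = 0.0177) and endothelial markers in 2 of 13 (3 adjusted over the list alone, camera adjusted p = 0.0467). B and plasma cell markers were positive in 3 of 8 (4 adjusted over the list alone, camera adjusted p = 0.00487), with Igha at 1.74 ± 0.47. Red blood cell markers passed in 0 of 7 cases, with a median of 0.71 (0 adjusted over the list alone, camera adjusted p = 0.0118). Of the S3 markers 1 of 7 was positive and 1 negative (4 and 1 adjusted over the list alone, camera adjusted p = 0.0118). Negative interactions were found for principal cell markers in 1 of 8 (5 adjusted over the list alone, camera adjusted p = 0.00658), for medulla markers in 1 of 8 (2 adjusted over the list alone, camera adjusted p = 0.00401) and for liver markers in 2 of 5 (4 adjusted over the list alone, camera adjusted p = 0.0211). Over these 9 lists the camera test gave adjusted p = 0.166 to 0.460 with an estimated correlation. Of all lists tested for the interaction, 24 passed by camera with the preset correlation and 14 by fry. The diabetic vehicle libraries, with the overlapping mitochondrially encoded and ribosomal RNA shares and their separate levels of Nnt (interaction -1.13 ± 0.06), enter this comparison as well. For Cdkn1a the interaction was -0.78 ± 0.33 (adjusted p = 0.139) and did not pass.

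The interaction passed for 1489 of 15808 genes by edgeR, 737 positive and 752 negative, and 341 had at least a 2-fold difference. Without scaling beyond library totals 79.3% were positive, against 49.5% with TMM. Leaving out diabetic vehicle replicate 4, chosen after the data were seen, gave 2242 genes, and gave 6796 with diabetes on vehicle and 4841 with PMX-53 in diabetes.

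**Figure D4:**
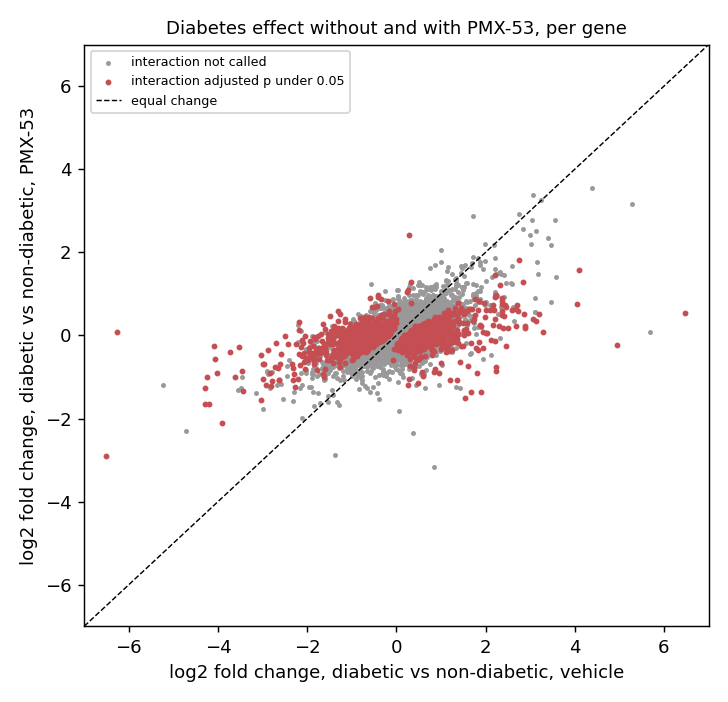
Log2 fold change with diabetes in mice on vehicle (horizontal axis) against that in mice on PMX-53 (vertical axis), 1 point per tested gene. Red points are the 1489 genes with an interaction adjusted p under 0.05, the dashed line marks equal change, and the correlation across genes was r = 0.592.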

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

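The tests of a substrain, of exchanged labels (all of them) and of a graded response were chosen only after the result was seen. So was the number of 60 divisions of the samples, which was set for running time after the draw of 100 had been seen.

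The 6 diabetic vehicle libraries lay beyond all 18 others at 590 of 15808 genes, 35 of them by more than 0.5 on the log2 scale, against 9, 3 and 26 genes for non-diabetic vehicle, non-diabetic PMX-53 and diabetic PMX-53, where chance gives 0.00149% of genes per group. An exchange of labels with non-diabetic vehicle libraries is argued against, since 6 of 6 diabetic vehicle libraries scored above all of them (0.131 to 0.373 against -0.323 to -0.189, mean log2 shift) on the 1587 genes called with diabetes on PMX-53, and so is an exchange of some libraries with non-diabetic PMX-53, again 6 of 6 (0.0523 to 0.305 against -0.208 to -0.110) on the 2363 genes called between diabetic PMX-53 and non-diabetic vehicle. An exchange of some libraries with diabetic PMX-53 is argued against, since the groups lay apart on the first 2 principal components of all tested genes. Diabetic vehicle libraries lay at 15.5 to 54.3 and 3.96 to 11.6, and diabetic PMX-53 libraries at -4.16 to 8.38 and -26.0 to -12.0. An exchange of the whole group with diabetic or non-diabetic PMX-53 stays open. If it was with non-diabetic PMX-53, the comparison of the vehicle groups would be the one that called 0 of 15808 genes. Although 0 of the 18 others lay within the diabetic vehicle range at Nnt, Wdfy1, Ide and Acad10 together, these genes were chosen for lying apart. A response graded with the other changes in these libraries stays open: over the 35 genes the median Spearman rho with the first principal component across the 6 libraries was 0.429, low in the 0.371 to 0.714 of 10000 random lists from 802 other called genes, whose median was 0.600. A substrain variant stays open as well, because Nnt carries a deletion in C57BL/6J, the copy number of Ide varies within C57BL/6J colonies, the labels name no substrain, and 6 of 6 diabetic vehicle libraries lay above all others at Nnt and below them at Ide, so that substrain and group cannot be told apart in the comparisons that use these 6.

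Nuclear respiratory chain and ATP synthase genes and cytosolic ribosomal protein genes were higher in the diabetic vehicle libraries, which also held more counts and larger mitochondrially encoded and ribosomal RNA shares, both of which count the mitochondrial ribosomal RNA genes. Transcript length and GC content were tested as a cause. The medians of 0.28 and 0.33 (log2) lay at percentile 100 of 10000 lists matched on expression, length and GC, whose medians were 0.06 and 0.08. Length was that of the longest annotated transcript. The matched genes were longer, at medians of 1342.5 and 1286 nucleotides against 1129 and 1107.5. The values argue against GC content as the whole cause, but cannot decide on a bias for short transcripts. Depth is argued against too, since with every library thinned to 10964992 counts 58 of the 58 respiratory and 38 of the 39 ribosomal protein genes that had risen still rose. Differences in RNA handling that follow the group, with small cytoplasmic and nuclear RNAs at a median of 0.53 with diabetes on vehicle and -0.46 with PMX-53 in diabetes, and diabetes itself stay open and were not tested.

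Each count of changed genes was set against divisions of the same libraries into groups of the same sizes, in a draw of 60 and in a draw of 100 per comparison, each with the real one included. For diabetes on vehicle 1 of 60 and 1 of 100 gave as many genes as 6363, and the highest others were 862 and 4323. For PMX-53 in diabetes it was 1 of 60 and 1 of 100 (4317, highest others 3298 and 2509), and for diabetes on PMX-53 1 of 60 and 1 of 100 (1587, highest other 74 in both), so in these 3 comparisons chance can be excluded at the 0.05 level. For the interaction, vehicle and PMX-53 labels were exchanged within diabetic and within non-diabetic mice, which tests for no effect of PMX-53 in either. Here 2 of 60 and 1 of 100 gave as many as 1489 (highest others 2103 and 777). Chance labels can be excluded at that level, in the draw of 60 by a small margin. The divisions cannot decide whether PMX-53 had equal effects in both. For PMX-53 in non-diabetic mice the real count is 0, which each of the 60 and of the 100 divisions reaches whatever it calls (highest others 20 and 2), so the divisions decide nothing there.

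Single libraries far from the other 5 of their group were found in 36 of 432 sets of 6 tested, where chance gives about 1 in 20, or 21.6, and 12 of the 36 were diabetic vehicle replicate 4. In that library Col19a1 was at 1.08 CPM (0.0635 to 0.222 in the 5 others), Cntnap5a at 1.85 (0.261 to 0.431), Col6a6 at 0.957 (0.0538 to 0.326), Pzp at 55.0 (1.42 to 5.90), Slco1a1 at 123 (1.33 to 19.2) and Slc22a7 at 31.8 (3.39 to 6.48). It also held Agt at 35.9 CPM (75.3 to 85.6), Rpl23 at 104 (122 to 131), Dscaml1 at 7.66 (2.81 to 4.17), Fcamr at 19.8 (7.01 to 10.4), Odc1 at 386 (161 to 234) and Kap at 5556 (145 to 1007). Other diabetic vehicle libraries far from their group were replicate 2 for Ndufb8 at 99.5 CPM (87.8 to 91.5) and replicate 5 for Mdm2 at 51.9 (55.2 to 57). Among non-diabetic vehicle libraries, replicate 4 held Ugt1a2 at 6.05 CPM (1.44 to 2.43) and C3 at 29.3 (12.9 to 19.0). Replicate 1 of that group held Cdkn1a at 5.56 (2.32 to 3.25), Igha at 142 (57.5 to 85.6) and Ndnf at 2.54 (0.221 to 1.04). Replicate 5 of that group held Car3 at 6.43 CPM (19.2 to 26.2), Anxa13 at 2.60 (7.28 to 7.92), Calb1 at 283 (131 to 172) and Acadl at 263 (195 to 215).

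Of the non-diabetic PMX-53 libraries, replicate 6 held Cox7a2 at 113 CPM (121 to 126), Aqp2 at 110 (29.1 to 42.7), Trf at 0.818 (1.32 to 1.42) and Wnt7b at 7.42 (0.614 to 1.21). Replicate 5 held Rplp1 at 182 CPM (154 to 162), Rpl23 at 111 (96.5 to 102), Slc12a3 at 1297 (915 to 1044) and Mdm2 at 50.8 (42.1 to 44.9). In the same group replicate 1 held Cox5b at 86.6 (75.8 to 78.7) and replicate 3 Ide at 127 (158 to 168). Of the diabetic PMX-53 libraries, replicate 2 held Aqp2 at 91.8 CPM (47.5 to 61.1) and Col6a3 at 43.8 (28.8 to 33.8), and replicate 6 held Acot3 at 15.7 (9.74 to 11.6).

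By edgeR's test of the interaction, the difference between PMX-53 and vehicle was not the same in diabetic and non-diabetic mice for 1489 genes. They included 60 of the 103 named genes tested. The diabetic vehicle libraries enter this test, so a trait of that group cannot be told apart from an effect of PMX-53. The interaction log2 fold change was -5.93 for Ugt1a2, -3.28 for C3, -3.21 for Ugt1a1, -3.09 for Cebpd, -3.05 for Wnt7b, -2.78 for Ddit4, -2.71 for Cyp4a14, -2.70 for Slc7a12, -2.70 for Nccrp1 and -2.68 for Gc. It was -2.01 for Per1, -1.64 for Acot3, -1.45 for Spp1, -1.38 for Aqp2, -1.26 for Wdfy1, -1.26 for Cp, -1.13 for Nnt, -1.10 for Ifi27, -0.95 for Kynu, -0.94 for Trf, -0.79 for Agt and -0.65 for Ptger3. Among metabolic genes it was -0.76 for Fbp2, -0.67 for Pkm, -0.55 for Eci1, -0.54 for Eno1 and -0.42 for Fdft1, and for the interferon-response gene Ddx58 it was -0.65. Respiratory and ribosomal protein genes were at -0.56 for Ndufa7, -0.54 for Cox5b, -0.52 for Rplp1, -0.50 for Uqcrq, -0.48 for Ndufb8, -0.48 for Uqcrb, -0.48 for Atp5o, -0.42 for Cox7a2, -0.42 for Rpl23 and -0.38 for Rps16. Positive interactions were 3.50 for Tmprss9, 3.33 for Col6a6, 2.64 for Col19a1, 2.54 for Ces2h, 2.22 for Acad10, 2.05 for Cpxm1, 1.94 for C4a, 1.93 for Slc22a7, 1.80 for Cntnap5a (2.51 without diabetic vehicle replicate 4) and 1.74 for Igha. Smaller positive values were 1.65 for Jchain, 1.56 for Cyp4a12a, 1.49 for Anxa13, 1.15 for Col1a1, 1.15 for Cyp4b1, 1.00 for Ide, 0.92 for Timd2, 0.82 for Gdf15, 0.76 for Timp3, 0.71 for Pdgfrb, 0.68 for Col6a3 and 0.63 for Kdr.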

How the results depend on the processing

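The fits without diabetic vehicle replicate 4, with thinned libraries and against non-diabetic vehicle, and the correlation of the diabetes effects under other settings, were chosen only after the data were seen. With a 2-fold threshold added, the counts were 934 for diabetes on vehicle, 517 for PMX-53 in diabetes, 150 for diabetes on PMX-53 and 341 for the interaction, because smaller changes are left out by construction. For diabetes on PMX-53 the count of 1587 became 871 without scaling beyond library totals and 2560 with limma voom and sample quality weights. The interaction count of 1489 became 2242 without diabetic vehicle replicate 4, and the cause was not tested for these 3 values. For PMX-53 in non-diabetic mice 0 became 1 without an expression filter, a gene with 61 counts in all. Of 88 list calls over the 5 comparisons 0 were made with an estimated correlation, and the cause was not tested. In total fry gave 87, a replicate block 90 and no scaling 106. Per comparison, however, camera and fry differed, with 21 and 32 lists for diabetes on vehicle and 25 and 35 for PMX-53 in diabetes. For PMX-53 without diabetes they called 11 and 0, for diabetes on PMX-53 7 and 6, and for the interaction 24 and 14. Every other count of genes stayed within 1.5 times under the alternatives run. There were 5403 to 6796 genes for diabetes on vehicle, 3580 to 4841 for PMX-53 in diabetes, and 2363 for diabetic PMX-53 against non-diabetic vehicle libraries. With every library thinned to the smallest total the counts were 5545, 3658, 0, 1375 and 1233. The replicate number as a block gave 6221, 4136, 0, 1483 and 1344 genes and changed no other call by over 1.5 times. The numbers share only a name: same-numbered libraries of different groups had a median correlation of deviations of 0.0109, 6 of 36 pairs were over 0.1, and 7 of 72 best matches were to the own number. The share of genes with opposite signs was 88.0% with divided diabetic vehicle libraries, 93.3% without scaling and 92.6% without diabetic vehicle replicate 4. The correlation of the diabetes effects was 0.589 and 0.583 under the last 2 settings. The difference in mitochondrially encoded share between vehicle groups, 6.89 percentage points, was 1.66 with ribosomal RNA left out, where the shares of both groups were smaller too. Of 2879 values of named genes under alternatives, 2811 kept direction and side of the threshold, 32 no longer passed, 36 newly passed and 0 changed direction. Depth limits what can be seen for genes near 1 CPM, which rest on about 11 to 22 counts per library.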

Other observations

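The list of p53 targets and the test of streptozotocin itself were chosen only after the result was seen.

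In each comparison most interferon-response genes did not pass the test. With diabetes on vehicle 11 of 38 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.0404, adjusted p = 0.760 with an estimated correlation), among them the RNA sensor gene Ddx58 at 0.87 ± 0.06 and Ifi27 at 1.19 ± 0.10 (log2). With PMX-53 in diabetes 11 of 38 fell and 2 rose (13 and 3 adjusted over the list alone, camera adjusted p = 0.0190, adjusted p = 0.573 with an estimated correlation), Ddx58 at -0.52 ± 0.06 and Ifi27 at -0.87 ± 0.10. In the interaction 9 were negative and 0 positive (10 and 0 adjusted over the list alone, camera adjusted p = 1.95e-04, adjusted p = 0.460 with an estimated correlation). With PMX-53 in non-diabetic mice the median was 0.14, and 0 of 38 rose (0 adjusted over the list alone, camera adjusted p = 9.04e-04, adjusted p = 0.673 with an estimated correlation).

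Genes of the circadian clock, of cholesterol synthesis and of the unfolded protein response moved both ways with diabetes on vehicle. Per1, a light- and glucocorticoid-responsive clock gene, rose by 1.86 ± 0.22 (log2, adjusted p = 9.71e-07) and was at -1.73 ± 0.22 with PMX-53 in diabetes (adjusted p = 8.90e-06). Of the clock genes 6 of 19 rose and 2 fell with diabetes (6 and 2 adjusted over the list alone, camera adjusted p = 0.734). Of cholesterol and fatty acid synthesis genes 11 of 28 rose and 8 fell (12 and 8 adjusted over the list alone, camera adjusted p = 0.415), with Fdft1, the squalene synthase gene, at 0.87 ± 0.08 and Insig1 at 0.96 ± 0.11. On PMX-53 these were at 0.44 ± 0.09 and 0.65 ± 0.12 with diabetes. The unfolded protein response list had 7 of 20 up and 8 down (8 and 9 adjusted over the list alone, camera adjusted p = 0.937), and the chaperone genes Pdia6 and Hsp90b1 were at -0.53 ± 0.10 and -0.57 ± 0.12 on vehicle and at -0.49 ± 0.10 and -0.55 ± 0.12 on PMX-53.

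A hypothesis is that p53 signalling may be raised in diabetic cortex with or without PMX-53. Of the p53 targets 20 of 26 rose and 2 fell with diabetes on vehicle (median log2 fold change 0.76, unadjusted camera p = 4.21e-05 with an estimated correlation), and 18 rose and 0 fell on PMX-53 (median 0.65, unadjusted camera p = 1.76e-07 with an estimated correlation). On vehicle and on PMX-53, Phlda3 was at 1.69 ± 0.14 and 1.65 ± 0.13, Ccng1 at 1.07 ± 0.07 and 0.99 ± 0.07 and Mdm2, the main negative regulator of p53, at 0.38 ± 0.05 and 0.27 ± 0.05. With PMX-53 in diabetes 4 rose and 5 fell. The list was chosen after the named genes had been seen in these data, so the camera p-values are no independent test of the hypothesis. On PMX-53 the median lay at percentile 100 of 10000 lists matched on expression, length and GC. That rank may follow from the choice of the list. The matched lists had a median of 0.00461, so genes of like length and GC did not rise on balance, which argues against both as the cause. Streptozotocin, which damages DNA, could itself raise these genes, and it cannot be told apart from diabetes, because 0 libraries come from injected mice without diabetes.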
